A study of Mus musculus with 2 samples.

How the data were processed

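Lung cells of 8-week-old WT and Sox17 conditional knockout (cKO) mice were labelled with hashtag antibodies, pooled and sequenced as one droplet-based single-cell library, per the labels. The deposited matrix held raw counts of unique molecular identifiers (UMIs) per gene and barcode, and raw counts per hashtag and barcode, made with Cell Ranger 7.0.0 on the mouse genome build mm10 per the submitters' processing notes. The annotation release and the cell-calling settings are not given in the sources used here. The second sample of the series, the hashtag library, had no file of its own here, and its counts were taken from the same matrix. The matrix held 26818 barcodes, 32285 genes and 4 hashtags, with 114727909 gene UMIs and 38450258 hashtag UMIs, a median of 3153 UMIs and 1569.5 genes per barcode.

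Of the 4 hashtags, WT was matched to the WT mice and S17TieKO to the Sox17 cKO mice by name alone, since the matrix lists no hashtag sequence to set against those in the labels. The other 2 hashtags, Gt and EH2, are not named in the labels, and the 12077 barcodes that carried one of them entered no comparison. Hashtag counts were transformed to centred log ratios, a mixture of 2 normal distributions was fitted per hashtag, and a barcode was positive above the point where the higher distribution became the more probable, given at least 50 hashtag UMIs. One hashtag was found on 4807 barcodes for WT and 3684 for S17TieKO, while 983 barcodes had none and 5267 had several and were left out. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs, which removed 230 WT and 229 cKO cells. Doublets were called with Scrublet as implemented in scanpy 1.11.5, at an expected rate of 8.31% derived from the barcodes with several hashtags. It called 376 cells (4.68%), 227 with the WT and 149 with the cKO hashtag, and these were removed. Of the 618 barcodes that passed the filter with both the WT and the cKO hashtag, Scrublet called 227 (36.7%), so part of the doublets within one hashtag stays in the data.

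Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without Sox17 and sex-linked genes, were scaled, reduced to 30 principal components and clustered with the Leiden algorithm (15 neighbours, resolution 1). A marker counted for a cluster at 2-fold or more over all other cells and with a UMI in at least 10% of its cells, and a class name needed 3 markers. After the data were seen, 2 rules were added for all classes: a cluster stayed unnamed with 3 markers of endothelial cells and 3 of a non-endothelial class, or with more markers of another class than of its own among its 10 leading genes. Class names stand for clusters that were like a cell type by these markers. Of the 26 clusters, numbers 14 and 15 stayed unnamed, and their shares are given in the results. No arterial cluster formed, and the endothelial cells were therefore clustered alone for the arterial share, a step also chosen after the data were seen.

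Levels are summed UMIs scaled to the UMI total of the same cells (CPM), with exact Poisson intervals. Shares have exact Clopper-Pearson intervals, and ratios of cKO-labelled over WT-labelled cells have exact conditional intervals, all at 95% and covering counting error only. A gene with 0 UMIs on one side was set against a floor of 3 counts, and where 0 cells had a UMI the share that 3 cells would make up is given as the limit. Shares of cells with a UMI and cycling shares were computed after thinning each cell to 1500 UMIs. A cell counted as cycling with UMIs of at least 2 genes of a list of G2/M genes. For each fixed gene list, the median log2 ratio over members with at least 20 UMIs was placed among the medians of 10000 random lists of the same size, matched on expression in 20 bins. Genes were named by a rule: Sox17, Sox7, Sox18, E2f1 and Bmpr2 in every class, up to 4 examples from each list (the highest UMIs, or the largest ratio with an interval that excludes 1; members named beyond this were chosen after their values were seen), and the 12 genes with the highest and the 12 with the lowest ratio in endothelial cells (5 each in other classes with at least 200 cells per hashtag). The ranking used the interval bound nearest 1, among genes with at least 50 UMIs and 20 CPM on the higher side, and left out mitochondrial, ribosomal, haemoglobin, immunoglobulin and sex-linked genes. A second ranking without genes of which 1 cell held over 5% of the UMIs was added after the data were seen. Gene positions are those of GENCODE vM21 on GRCm38, the build also named mm10. The filters, clustering settings, markers, gene lists, naming rule for genes and the alternative settings not named as added were chosen before the data were examined.

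The labels do not state the number of mice, and all cells of one hashtag were treated as 1 sample. No test between genotypes was made and no p-value was computed. The Sox17 ratio in endothelial cells had an interval that included 1, which leaves the label unchecked, and the groups are named WT-labelled and cKO-labelled cells for this reason.

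The calculations were tested on simulated data. For WT-labelled against cKO-labelled endothelial cells, summed counts of 11417 genes were drawn from Poisson distributions with 200 of them set to known folds. The intervals assume the same distribution, so their coverage checks the calculation only. Spread between cells or mice was not simulated. The intervals held the true fold in 96.0% of genes with a fold of 1, and in 94, 96, 98 and 92% of genes set to 0.25, 0.5, 2 and 4-fold. The ranking, run on 9111 genes, returned 12 genes set higher among the 12 ranked highest and 12 genes set lower among the 12 ranked lowest. A simulated list set 2-fold higher gave a median log2 ratio of 0.99, and 0 of the other lists lay outside the range of 95% of random lists. In simulated counts of 4 hashtags with equal signal, 99.2% of single barcodes received their hashtag and 17.2% of barcodes with 2 hashtags were called as 1. The deposited hashtags differed in their UMI totals (6936275 for WT and 12289280 for S17TieKO), so these shares need not hold for them. Alternatives covered the cell filter, doublets, clustering, hashtag rule, normalization, thinning depth, the definition of endothelial cells and the denominator of shares. Software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.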

Results

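Single-cell RNA sequencing was applied to lung cells of WT mice and mice with a conditional knockout of Sox17, a transcription factor of the endothelium with a known role in arterial identity. The title of the series names E2f1, a transcription factor that promotes entry into S phase, as a mediator of pulmonary hypertension in Sox17 deficiency. After filtering, 4350 cells carried the WT hashtag, with 14205716 UMIs and a median of 2425 per cell, and 3306 cells carried the cKO hashtag, with 11252330 UMIs and a median of 2656 per cell. Each hashtag stood for 1 sample, so no difference had a replicate check, and the intervals given in brackets are exact 95% intervals of counting error only.

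The first comparison asked whether the labels show in the targeted gene. Sox17 (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354, minus strand, GRCm38) stood at 158 CPM (144 to 174) in WT-labelled and 143 CPM (129 to 157) in cKO-labelled endothelial cells, a ratio of 0.902 (0.788 to 1.03) from 457 and 418 UMIs. In general capillary cells, the main endothelial class of the alveolar wall, the ratio was 1.05 (0.915 to 1.21). That class joined cluster 0, with 542 WT-labelled and 334 cKO-labelled cells, and cluster 2, with 416 and 420. In venous cells Sox17 was lower in the cKO-labelled cells, at 40.8 against 99.1 CPM (ratio 0.412, 0.174 to 0.907), from 10 against 22 UMIs. In aerocytes, the capillary cells specialised in gas exchange, the ratio was 1.49 (0.744 to 3.18) from 12 WT-labelled and 31 cKO-labelled UMIs. Outside the blood vessel classes Sox17 had 17 and 9 UMIs in fibroblasts (ratio 0.549, 0.216 to 1.30). It had 9 and 1 in alveolar macrophages (6.93 and 0.937 CPM, ratio 0.135, 0.00309 to 0.976). Pericytes had 4 and 10 and each other class at most 5 per label. The endothelial factor Sox7 had 25 and 21 UMIs in fibroblasts, 3 and 2 in alveolar macrophages and 12 and 19 in pericytes. Endothelial RNA in these classes was therefore not told apart from Sox17 of their own. After thinning to 1500 UMIs, 19.7% of 978 WT-labelled and 20.4% of 904 cKO-labelled endothelial cells had a Sox17 UMI, with 180 and 127 shallower cells left out. Without thinning, the shares were 26.5% and 27.7%, at median depths of 2157.5 and 2459 UMIs. T cells, which should lack Sox17, had a UMI in 2 of 490 thinned WT-labelled cells and in 0 of 406 cKO-labelled cells, which allows a share of up to 0.739% by the floor of 3 counts, at median depths of 3374 and 3225 UMIs. The part of Sox17 that was deleted is not given in the sources used here, and counted tags outside it would check nothing. Since the endothelial ratio of Sox17 was close to 1, with an interval that included 1, the label is not checked by these counts and every direction below is a direction between hashtag labels.

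The related SoxF factors Sox7 and Sox18, which share endothelial functions with Sox17, went in opposite directions by small amounts. Sox7 had a ratio of 0.841 (0.753 to 0.938) and Sox18 a ratio of 1.15 (1.01 to 1.30) in endothelial cells. The 3 SoxF factors had a median log2 ratio of -0.15, at percentile 22.2 of random lists, and 0.08 in general capillary cells alone. Bmpr2, the BMP receptor most often mutated in heritable pulmonary arterial hypertension, stood at 1970 CPM (1919 to 2022) and 1968 CPM (1917 to 2019), a ratio of 0.999 (0.963 to 1.04). Bmpr2 was lower in the cKO-labelled cells among B cells (0.412, 0.198 to 0.847), from 19 and 16 UMIs at 36.7 and 15.1 CPM. It was also lower among smooth muscle cells (0.333, 0.157 to 0.642), from 55 and 11 UMIs in 18 and 10 cells. Among classical monocytes it was higher (1.52, 1.15 to 2.00), from 182 and 76 UMIs. In every other class the interval included 1.

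**Figure D1:**
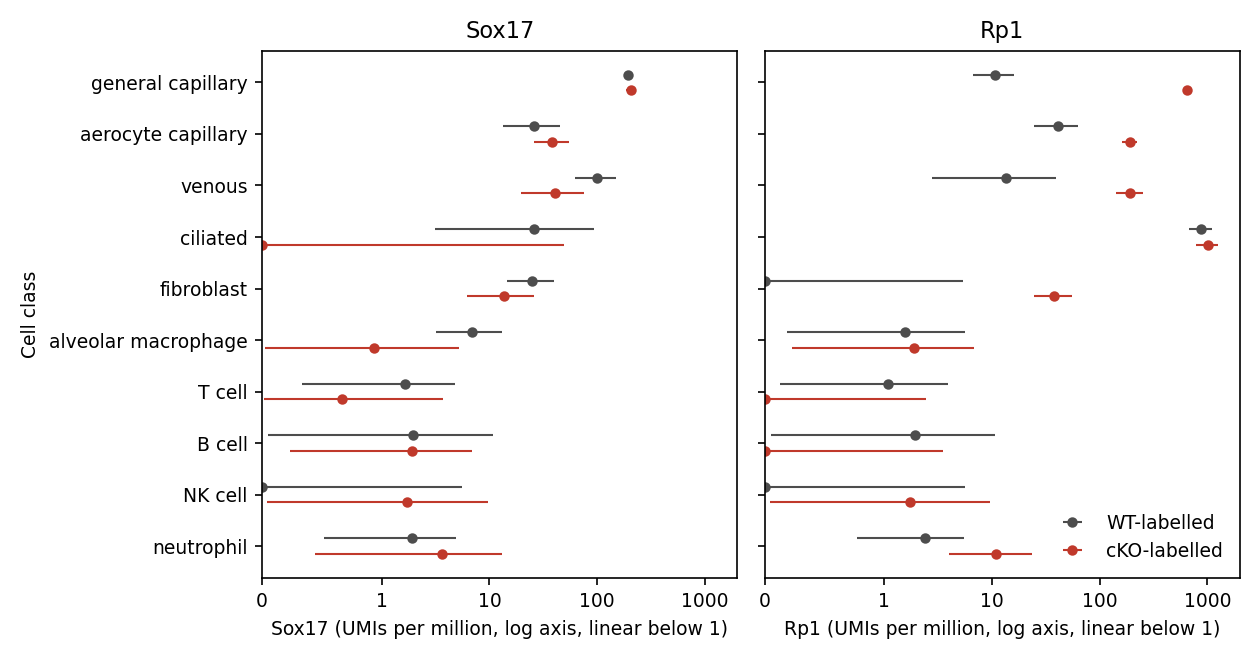
Level of Sox17 (left) and Rp1 (right) in CPM, on a log axis that is linear below 1, per cell class and label, with exact 95% Poisson intervals. In general capillary cells Sox17 lies at 194 CPM in WT-labelled and 205 CPM in cKO-labelled cells, while Rp1 lies at 10.6 and 644 CPM.

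The next comparison described which cells the labelled lungs gave. Neutrophils made up 25.4% (24.1 to 26.7) of WT-labelled and 9.26% (8.29 to 10.3) of cKO-labelled cells, and B cells 4.97% (4.34 to 5.65) and 13.8% (12.6 to 15). The ratios were 0.365 (0.320 to 0.414) for neutrophils and 2.77 (2.35 to 3.27) for B cells. The monocytes split: classical monocytes, the Ly6c2-positive class, had 8.83% and 3.75% (ratio 0.425, 0.344 to 0.522), and nonclassical monocytes, which patrol vessels, had 4.18% and 7.62% (ratio 1.82, 1.5 to 2.22). T cells (11.7% and 12.7%), NK cells (5.82% and 6.72%), fibroblasts (3.36% and 3.93%) and alveolar macrophages (3.43% and 3.42%) had ratios whose intervals included 1. Among the rarer classes, pericytes had 16 and 26 cells (ratio 2.14, 1.10 to 4.27), and plasma, smooth muscle, ciliated, alveolar epithelial, lymphatic and basophil or mast cells had intervals that included 1. Endothelial cells made up 26.6% and 31.2% of all cells (ratio 1.17, 1.08 to 1.28) and 35.7% and 34.4% of cells other than neutrophils (ratio 0.963, 0.885 to 1.05). The unnamed cluster 14, with markers of endothelial and alveolar type 1 cells, held 1.79% and 2.51%, and the unnamed cluster 15, with markers of macrophages and dendritic cells, 1.59% and 1.85%. Neutrophils had median depths of 1791.5 and 1634 UMIs, close to the filter at 1000 UMIs. With the hashtag rule that asks for 3 times the next hashtag, the ratio was 0.649 for neutrophils, 2.75 for nonclassical monocytes, 2.24 for NK cells, 0.784 for T cells, 0.896 for fibroblasts and 0.385 for alveolar macrophages. The T-cell ratio was also below 1 (0.899) with at least 1000 genes per cell and at most 10% mitochondrial UMIs, and among cells other than neutrophils the ratios of T cells (0.891), NK cells (0.949) and fibroblasts (0.963) were below 1.

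**Figure D2:**
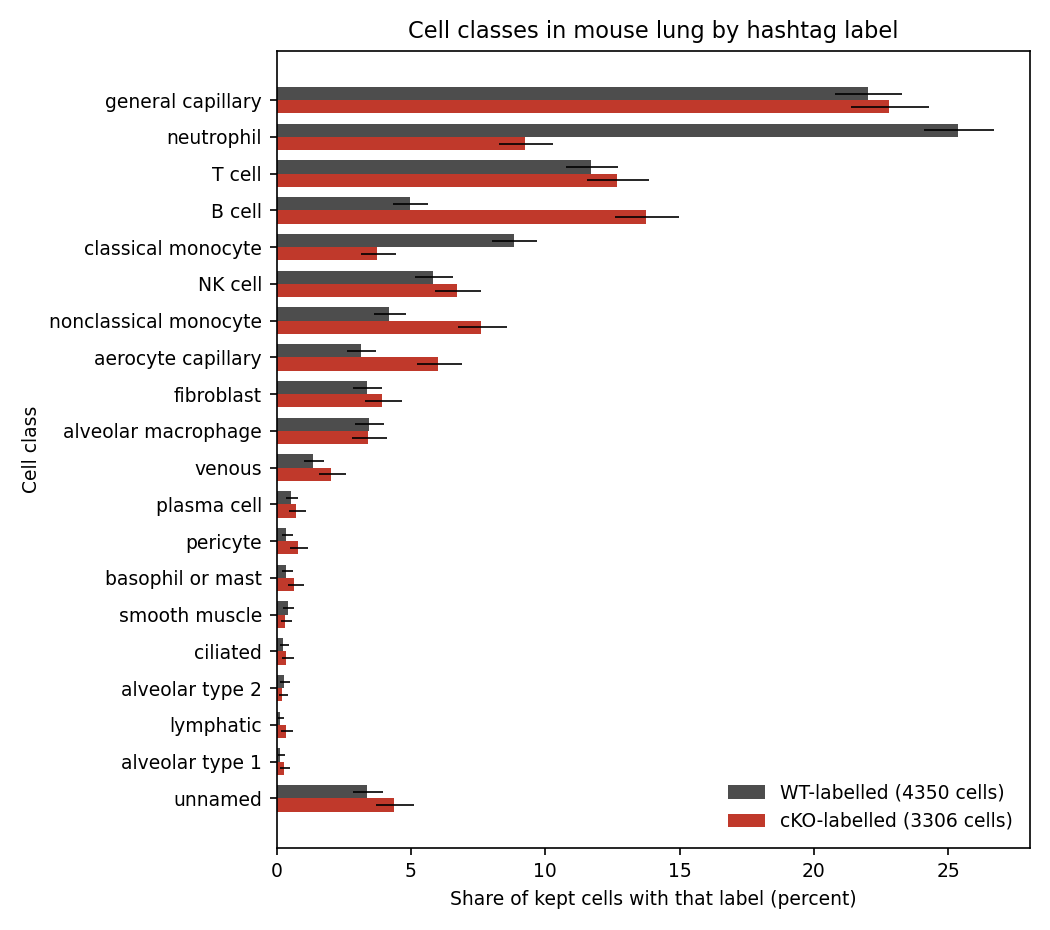
Share of kept cells per cell class in percent, for 4350 WT-labelled and 3306 cKO-labelled cells, with exact 95% binomial intervals as lines. Neutrophils (25.4% and 9.26%) and B cells (4.97% and 13.8%) stand furthest apart among the larger classes.

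Within the endothelium, the capillary classes differed between labels and arterial cells were rare in both. General capillary cells made up 82.7% (80.4 to 84.9) of 1158 WT-labelled and 73.1% (70.3 to 75.8) of 1031 cKO-labelled endothelial cells. Aerocytes made up 11.7% (9.95 to 13.7) and 19.3% (16.9 to 21.8), a ratio of 1.64 (1.31 to 2.06), and venous cells 5.09% and 6.5% (ratio 1.28, 0.885 to 1.84). When endothelial cells were clustered alone, the arterial cluster held 12 WT-labelled cells (1.04%) and 32 cKO-labelled cells (3.10%), a ratio of 3.0 (1.5 to 6.39), which was 1.90 when these cells were clustered at resolution 2 and 5.80 for the arterial cluster of all cells at that resolution. The general capillary class was spread over 2 clusters in different proportions. Cluster 0 held 542 of the 958 WT-labelled and 334 of the 754 cKO-labelled cells. Cluster 2 held 416 and 420, with Cxcl12, Edn1, Sema3g, Bmp6, Ntrk2, Smad6 and the arterial marker Hey1 among its leading genes.

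E2f1 (chromosome 2, 154559407 to 154569892, minus strand), the factor in the series title, was close to the detection limit in endothelial cells. It had 5 UMIs (1.73 CPM) in WT-labelled and 11 UMIs (3.76 CPM) in cKO-labelled endothelial cells, a ratio of 2.17 (0.695 to 7.96), so a difference was not detectable at this depth. With hashtag counts scaled to their medians the ratio was 4.13. Thinned endothelial cells had an E2f1 UMI in 2 of 978 and 4 of 904 cells (5 of 1158 and 9 of 1031 without thinning), and thinned T cells in 4 of 490 and 3 of 406. The highest summed count of E2f1 was in alveolar macrophages, with 45 and 29 UMIs (34.6 and 27.2 CPM, ratio 0.785, 0.474 to 1.28). Cycling cells were as rare, with 4 of 978 WT-labelled (0.409%) and 5 of 904 cKO-labelled (0.553%) thinned endothelial cells, a ratio of 1.35 (0.291 to 6.82), and 180 and 127 shallower cells left out. That ratio was 0.527 under the same stricter cell filter and 2.34 after thinning to a greater depth. Without thinning, the counts were 14 of 1158 and 17 of 1031. Neutrophils, which do not divide once mature, had 6 of 855 and 2 of 200 by the same measure. Whether the neutrophils counted were mature was not tested, so they set no background level for the endothelial counts.

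The median of the list of G1/S genes lay above 0 in the cKO-labelled endothelial cells, within the range of random lists, and a count per cell gave a ratio near 1. Here and below, a member counts as higher or lower at a log2 difference of 0.32, a rule of size and not a test. Of 22 measured G1/S and E2F target genes, 9 were higher, 2 lower and 11 between, with a median log2 ratio of 0.28 at percentile 96.2, inside the range of 95% of random lists (-0.15 to 0.30). Counted per cell after thinning, 30 of 978 WT-labelled and 29 of 904 cKO-labelled cells had UMIs of at least 3 genes of this list, a ratio of 1.05. Dut, which keeps uracil out of DNA, had a ratio of 2.01 (1.27 to 3.25) and Rfc3, a clamp loader subunit, 1.6 (1.06 to 2.44), while Pcna, the sliding clamp, had 1.09 (0.958 to 1.24). Of 8 measured G2/M genes, 4 were higher and 2 lower (median 0.25, percentile 74.2, but -0.15 after thinning to 1500 UMIs and 0.85 with capillary, aerocyte and venous cells weighted equally), among them Mki67, a marker of dividing cells, with 3 and 18 UMIs (ratio 5.92, 1.73 to 31.3) and 28.6% of its UMIs in 1 cell. Of 10 measured E2F family and pocket protein genes, 3 were higher and 2 lower (median 0.02, percentile 31.7, and -0.08 over members with at least 100 UMIs), with E2f7, a repressing E2F, at 2.51 (1.21 to 5.59) and Rb1 at 0.954 (0.849 to 1.07).

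Vessel identity genes were split inside each group. Of 21 measured arterial and Notch genes, 9 were higher, 4 lower and 8 between in the cKO-labelled endothelial cells, and their median log2 ratio of 0.23 stood at percentile 99.9. Gja5, an arterial gap junction protein, had a ratio of 3.24 (1.75 to 6.38), Fbln5, an elastic fibre protein, 2.57 (1.86 to 3.59), and Cxcl12 2.19 (2.05 to 2.34), a chemokine that leads cluster 2 and was also among the markers by which clusters 0 and 2 were named general capillary. Tm4sf1, with the most UMIs of the list, had 1.17 (1.11 to 1.23). The 4 lower members, named after their values were seen, were Cxcr4 (0.548, 0.322 to 0.912), the Notch ligands Dll1 (0.586, 0.489 to 0.70) and Jag1 (0.779, 0.603 to 1.004, which includes 1), and the arterial ephrin Efnb2 (0.763, 0.709 to 0.821), while a further Notch ligand, Jag2, had 1.56 (1.16 to 2.10). Of 9 venous identity genes, 1 was higher and 3 were lower (median -0.13, percentile 9.89), with Nr2f2, a venous transcription factor, at 1.63 (1.28 to 2.08) and Aplnr at 0.487 (0.367 to 0.641). Aplnr was also a fixed general capillary marker, and it counted for cluster 0 and not for cluster 2. Of 12 capillary identity genes, 5 were higher and 5 lower (median 0.06, percentile 88.3, but -0.20 at percentile 0.85 with the capillary, aerocyte and venous classes weighted equally). The higher ones were aerocyte markers such as Car4 (1.70, 1.58 to 1.84) and Apln (2.68, 2.04 to 3.54), and the lower ones genes of general capillary cells such as Gpihbp1, which anchors lipoprotein lipase (0.622, 0.583 to 0.663), and Kit (0.593, 0.534 to 0.659). The shares of aerocytes and arterial cells differed in the same direction, with ratios of 1.64 and 3.0.

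MHC class II genes, which present antigen and are expressed by part of the lung endothelium, were all higher in the cKO-labelled endothelial cells. All 7 measured members were higher, with a median log2 ratio of 1.17 at percentile 100. Cd74, the invariant chain, had a ratio of 3.35 (3.15 to 3.57), H2-Eb1 2.28 (2.02 to 2.57), Ciita, the master activator of the class, 2.26 (1.65 to 3.12), and H2-Aa 2.05 (1.85 to 2.26). The B-cell marker Cd79a, named after its values were seen, had 35 and 24 UMIs in the same cells (ratio 0.676, 0.385 to 1.17), and the marker list of other cell types had a median of -0.06 (percentile 25.2, and -0.29 in general capillary cells alone), with 3 of 11 members higher and 5 lower. Of 14 adhesion and inflammation genes, 7 were higher and 0 lower (median 0.32, percentile 99.9), with Selp, the selectin of Weibel-Palade bodies, at 1.91 (1.66 to 2.21) and Icam1 at 1.5 (1.41 to 1.59). Of 14 interferon response genes, 1 was higher and 2 were lower (median -0.13, percentile 6.55), with Ifit2 at 3.50 (1.76 to 7.57) and Usp18 at 0.758 (0.593 to 0.968). Of 17 dissociation and immediate-early genes, 1 was higher and 0 lower (median 0.02, percentile 83.4, with both signs among the alternative settings), with Fos at 1.26 (1.22 to 1.30).

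Signalling genes tied to pulmonary hypertension differed one by one. Edn1, the vasoconstrictor endothelin, had a ratio of 2.27 (2.01 to 2.58), Kdr, the main VEGF receptor, named after its values were seen, 1.73 (1.61 to 1.86), and Atp13a3 2.21 (1.71 to 2.88), whereas Ptgs1, a cyclooxygenase, had 0.451 (0.359 to 0.563). Of the 27 measured vasoactive and pulmonary hypertension genes, 10 were higher, 5 lower and 12 between (median 0.03, percentile 71.2, but 0.22 at percentile 99.9 after thinning to 1500 UMIs). Of 18 BMP signalling genes, 5 were higher and 2 lower (median 0.19, percentile 99.5), with Bmp4 at 2.20 (1.63 to 2.98), the BMP target Id3 at 1.31 (1.23 to 1.41), and the ligand Bmp6 at 0.686 (0.639 to 0.737). Of 16 TGF-beta and endothelial-to-mesenchymal genes, 7 were higher and 1 lower (median 0.21, percentile 96.7), with Tgfbr2, a TGF-beta receptor, at 1.55 (1.31 to 1.82). Of 15 Wnt and beta-catenin genes, 6 were higher and 2 lower (median 0.18, percentile 93.3, but -0.06 after thinning to 1500 UMIs), with Ccnd1, a cyclin, at 2.24 (1.94 to 2.60) and the receptor Fzd4 at 0.753 (0.679 to 0.834).

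The lists of matrix and metabolism had medians above 0, and those of cell death and junctions had medians near 0, of either sign among the alternative settings, with single members higher and lower. Of 13 extracellular matrix and contractile genes, 9 were higher and 0 lower (median 0.54, percentile 99.8), with Eln, elastin, at 1.89 (1.62 to 2.20) and Col4a2, a basement membrane collagen, at 1.45 (1.32 to 1.6). Several of these had few UMIs, such as the fibroblast gene Col1a2 with 6 and 19. Of 16 glycolysis and hypoxia genes, 11 were higher and 2 lower, plus 3 between (median 0.44, percentile 100), with Pkm at 1.56 (1.31 to 1.86) and Aldoa at 1.51 (1.32 to 1.73). The summed CPM of this list had a ratio of only 0.978, since its most abundant member Epas1, a hypoxia-inducible factor, was lower (0.818, 0.789 to 0.848). Of 15 pro-apoptotic genes, 5 were higher and 2 lower (median -0.02, percentile 30.6), with Bax at 1.42 (1.20 to 1.68) and Pmaip1 at 0.713 (0.561 to 0.905). Of 9 anti-apoptotic genes, 1 was higher and 1 lower (median -0.04, percentile 37.9), with Birc3 at 0.765 (0.664 to 0.881). Of 11 endothelial junction genes, 2 were higher and 1 lower (median 0.10, percentile 90.8), with Cdh5, VE-cadherin, at 0.941 (0.899 to 0.984) and Jam2 at 1.41 (1.19 to 1.68).

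**Figure D3:**
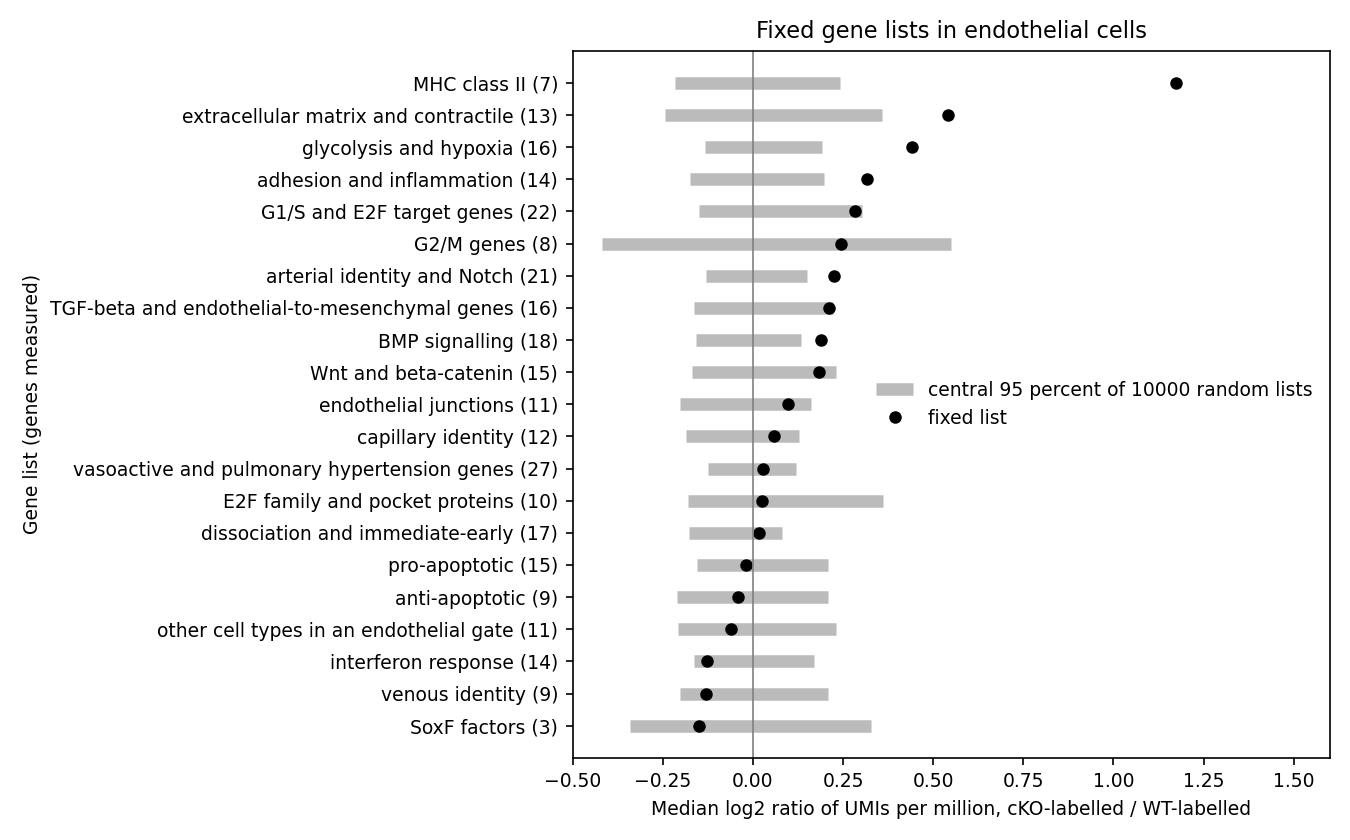
Median log2 ratio of cKO-labelled over WT-labelled endothelial cells for each fixed gene list (points), with the number of measured genes in brackets and the central 95% of 10000 random lists as grey bars. MHC class II (1.17), extracellular matrix and contractile genes (0.54) and glycolysis and hypoxia (0.44) lie furthest above their bars.

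Ranked over all genes in endothelial cells, the gene furthest from 1 that many cells shared was Rp1, a microtubule-associated protein of photoreceptors and cilia. Rp1 (chromosome 1, 3999557 to 4409241, minus strand) is annotated beyond the 3′ end of Sox17 on the same strand. It had 46 UMIs in WT-labelled and 1390 in cKO-labelled endothelial cells, 15.9 and 475 CPM, a ratio of 29.8 (22.2 to 40.9), and 59.2 with the rule of 3 times the next hashtag. After thinning, 10 of 978 and 386 of 904 endothelial cells had an Rp1 UMI (18 of 1158 and 574 of 1031 without thinning), against 0 of 490 T cells, which allows up to 0.612% by the floor of 3 counts, and 0 of 406, which allows up to 0.739%. Rp1 was also counted more often under the cKO label in some classes outside the endothelium, with 0 and 25 UMIs in fibroblasts, 0 and 24 in pericytes, 0 and 6 in basophil or mast cells and 5 and 6 in neutrophils (ratio 4.57, 1.16 to 18.9), while ciliated cells had 67 and 76. The endothelial factor Sox7 also had 25 and 21 UMIs in fibroblasts, 12 and 19 in pericytes and 4 and 5 in neutrophils. In basophil or mast cells Sox7 had 1 and 4. Endothelial RNA in these classes was therefore not told apart from Rp1 of their own. Adcy2, an adenylyl cyclase, had a ratio of 27.2 (17.3 to 45.6), and Cyp1a1, the xenobiotic enzyme induced by the aryl hydrocarbon receptor, 12.4 (9.52 to 16.6). Gm50250 had 10.2 (5.14 to 23.0), with 6.86% of its UMIs in 1 cell, and Ntrk2, the BDNF receptor, 4.62 (3.84 to 5.6). The airway secretory genes Bpifa1, Scgb3a2, Scgb3a1, Scgb1a1, Reg3g and Cyp2f2 also ranked among the 12 highest, with ratios from 20 to 192, as did Bpifb1 (0 and 83 UMIs, 27.3-fold higher against a floor of 3 counts, with an exact lower bound of 21.7). For each of these 7 genes a single cell held 83.5% to 99.1% of the UMIs, and Scgb1a1, at 20.8, had a ratio of 0.732 without that cell and 4.06 with doublets kept. Haemoglobin genes stood at 0.137% and 0.00355% of endothelial UMIs, but 2 WT-labelled general capillary cells held 3932 of the haemoglobin UMIs. Without these cells the counts went the other way, with 19 and 74 haemoglobin UMIs in general capillary cells, beside 5 and 23 in aerocytes.

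Without genes that 1 cell dominates, a ranking added after the data were seen, the list was completed by Cd74, Sparcl1, a matricellular protein (3.23, 2.83 to 3.70), Adam23 (3.50, 2.45 to 5.10), Tcof1 (3.08, 2.42 to 3.94), Mgll, a monoacylglycerol lipase (2.68, 2.36 to 3.05), the taurine transporter Slc6a6 (2.64, 2.34 to 2.99), Ankrd37 (3.05, 2.15 to 4.38) and Glo1, which detoxifies methylglyoxal (2.66, 2.12 to 3.37). The gene with the lowest ratio was Gdpd3, a lysophospholipase D (chromosome 7, 126766334 to 126775649), with 303 and 35 UMIs (0.114, 0.0779 to 0.162). Next came the sulfotransferase Sult1a1 (chromosome 7, 126672865 to 126676432), at 0.159 (0.0998 to 0.244). Cyp26b1, which degrades retinoic acid (0.292, 0.226 to 0.375), and Rarb, a receptor of it (0.389, 0.272 to 0.550), were lower. Of the Rarb UMIs 1 cell held 7.83%, so Rarb is not in the added ranking. The receptors Glp1r, for glucagon-like peptide (0.366, 0.321 to 0.415), and Adgrl3, an adhesion receptor (0.444, 0.428 to 0.462), were lower with 882 and 327 and with 8728 and 3935 UMIs. The remaining lowest genes were 4930554G24Rik (0.366), Hs3st1 (0.348), the peptide gene Grp (0.282), Lilrb4a (0.320), Gprin3 (0.333) and Pola2 (0.377), and in the added ranking Slc16a9 (0.485) and Ptgs1 (0.451). Lilrb4a had 6.60% of its UMIs in 1 cell and is not in the added ranking either. When endothelial cells were clustered alone, Rp1, Ntrk2, Adam23, Slc6a6 and Edn1 were among the leading genes of a cluster of 13 WT-labelled and 171 cKO-labelled cells, and Sult1a1 of one with 159 and 25. The clustering set aside only Sox17 and sex-linked genes, so genes of this ranking could shape these clusters. They are therefore no separate check of the ranking. Mitochondrial genes took 2.12% and 2.25% of endothelial UMIs, ribosomal protein genes 6.45% and 6.52%, and immunoglobulin genes 0.0176% and 0.0165%.

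**Figure D4:**
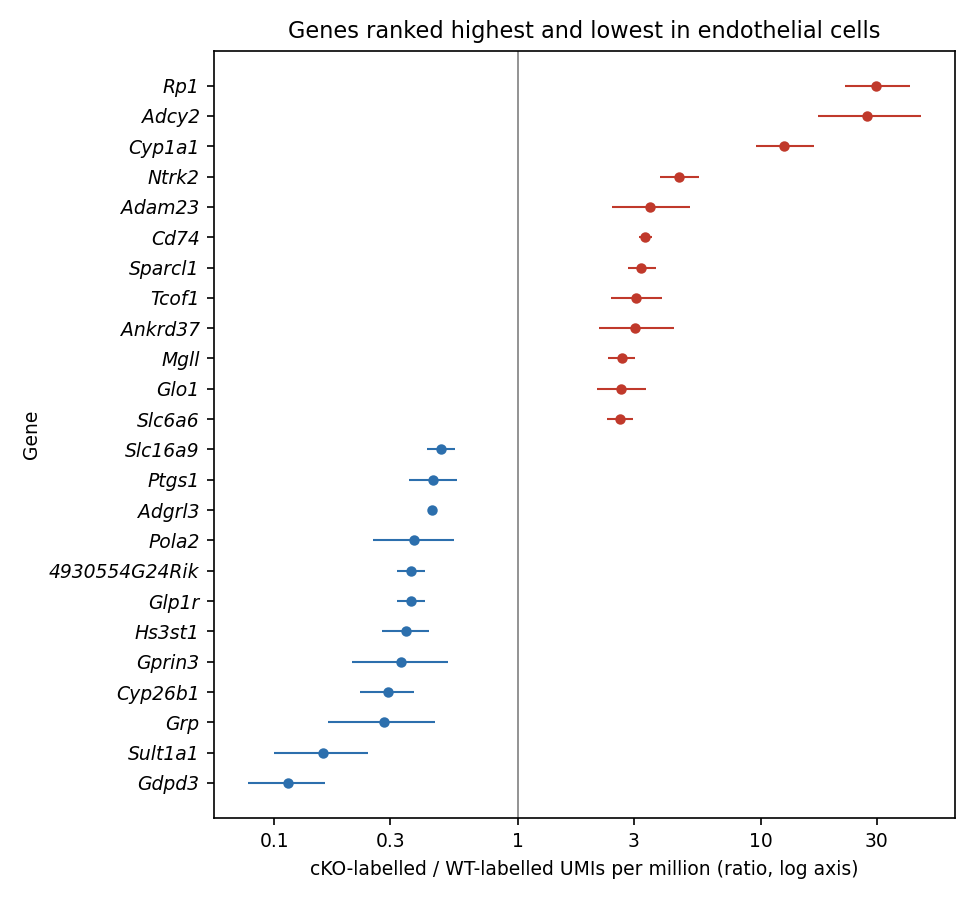
Ratio of CPM, cKO-labelled over WT-labelled endothelial cells on a log axis, for the 12 highest and 12 lowest genes of the ranking without genes dominated by 1 cell, with exact 95% intervals. Rp1 lies at 29.8 and Gdpd3 at 0.114.

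In general capillary cells alone, split over clusters 0 and 2 as above, Rp1 had a ratio of 61.0 (40.4 to 96.6), Adcy2 37.6 (22.2 to 69.3), Cyp1a1 13.8 (9.02 to 22.2) and Ntrk2, itself among the leading genes of cluster 2, 5.41 (4.46 to 6.61). Bpifa1, Scgb3a2, Scgb3a1 and Scgb1a1 ranked among the 5 highest there through the same dominance of 1 cell, with shares of 93.8% to 99.2%. The lowest were Gdpd3 (0.134), Sult1a1 (0.173), 4930554G24Rik (0.286), Slc16a9, a carnitine efflux transporter (0.345), and Hs3st1 (0.320).

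In neutrophils, Ltf, Ngp and Camp were among the genes higher in the cKO-labelled cells. Ltf (lactotransferrin) had a ratio of 5.29 (4.63 to 6.05), Ngp 4.79 (4.51 to 5.10) and Camp (cathelicidin) 4.08 (3.79 to 4.41), and these genes lead cluster 17, which held 24 of 1104 and 26 of 306 neutrophils. Fmnl2 (4.61), Nt5e (4.16) and, without genes that 1 cell dominates, Thbs1 (2.62, 2.47 to 2.78), Cd177 (2.89, 2.23 to 3.74), Syne1 (2.53), Odc1 (2.45) and Btbd9 (2.45) were also higher. Wfdc17 (0.160, 0.143 to 0.179), the stefins Stfa1 (0.0732) and Cstdc5 (0.0742), Gdpd3 (0.182), Ifitm1 (0.315, 0.288 to 0.345), Igfbp6 (0.254) and the chemokine receptor Cxcr1 (0.203) were lower. For Stfa1 and Cstdc5 the top cell of the gene held 13.7% and 12.1% of the UMIs. For Ltf, Ngp, Camp, Fmnl2 and Nt5e it held 6.25% to 10.2%.

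In lymphocytes, Dnah8, Btbd9 and Glo1, neighbours on chromosome 17, were among the higher genes. Dnah8, an axonemal dynein (30624354 to 30877365), had a ratio of 4.59 (3.55 to 6.01) in T cells and 35.8 (6.22 to 1431) in B cells, the latter from 1 and 73 UMIs. Its neighbour Btbd9 (30215524 to 30576488) had ratios of 2.22 (2.02 to 2.44) in T cells, 2.13 (1.80 to 2.54) in B cells and 1.77 (1.51 to 2.07) in NK cells, and Glo1, between both (30584936 to 30626871), 2.94 (1.67 to 5.38) in NK cells. Gdpd3 had 190 and 1 UMIs in T cells (0.00645, 0.000163 to 0.0364). In NK cells Ifng (0.351, 0.195 to 0.603), Nfkbia (0.546, 0.456 to 0.651), Icam1 (0.508, 0.387 to 0.661), Junb (0.596, 0.512 to 0.693) and Dusp1 (0.541, 0.421 to 0.692) were lower, with Frmd5, Angpt1, Sgk1 and Mir155hg between 0.321 and 0.424, while Rpn1 (2.87), Sema6a (2.24) and Mgp (2.22, 48.1% of its UMIs in 1 cell) were higher. B cells had higher Agbl1 (5.98), Snx18 (4.80) and Ensa (3.61) and lower Hspa1b (0.194), Apoe (0.457), 2610035D17Rik (0.468), Cables1 (0.365) and Atxn1 (0.465). T cells had higher Palld (10.6), Hist1h1b (4.69), Mt2 (4.73) and Car1 (135), of which 1 cell held 42.7% to 99.1% of the UMIs, and lower Ly6a (0.518), Gab3 (0.470), Cobll1 (0.350) and Kcnq5 (0.524). In B cells the top cell of a gene held 23.3% of the UMIs for Hspa1b, 10.7% for Cables1 and 10.9% for Atxn1. In NK cells it held 14.3% for Ifng, 13.4% for Frmd5 and 10.7% for Mir155hg. Agbl1, Snx18 and Dnah8 in B cells, Angpt1, Rpn1 and Sema6a in NK cells, and Cobll1 and Kcnq5 in T cells also exceeded the 5% limit.

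Summed over their members, several lists differed by cell class. The adhesion and inflammation list had a summed CPM ratio of 1.21 (1.18 to 1.24) in endothelial cells but 0.243 (0.232 to 0.254) in classical monocytes, 0.460 (0.441 to 0.480) in nonclassical monocytes, 0.588 (0.569 to 0.608) in alveolar macrophages and 0.736 (0.723 to 0.748) in neutrophils. The dissociation and immediate-early list had 1.03 (1.02 to 1.04) in endothelial cells, 0.581 (0.558 to 0.604) in classical monocytes, 0.655 (0.632 to 0.678) in nonclassical monocytes and 0.627 (0.611 to 0.644) in alveolar macrophages. MHC class II had 2.65 (2.55 to 2.77) in endothelial cells, 0.988 (0.960 to 1.02) in B cells, 1.63 (1.47 to 1.81) in alveolar macrophages, 0.821 (0.763 to 0.882) in nonclassical and 0.555 (0.513 to 0.600) in classical monocytes, and 4.96 (4.10 to 6.03) in fibroblasts, where the B-cell marker Cd79a also had 7 and 39 UMIs. Cd74 was higher in each of the main endothelial classes. Its ratio was 4.02 (3.76 to 4.30) in general capillary cells, which joined clusters 0 and 2 in proportions that differed by label. It was 2.85 (2.29 to 3.57) in venous cells and 2.16 (1.66 to 2.84) in aerocytes. Other members were less even, with intervals that included 1 for H2-Aa in aerocytes (1.14, 0.791 to 1.66) and venous cells (1.38, 0.995 to 1.93) and for H2-Eb1 in aerocytes (1.53, 0.962 to 2.5).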

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

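Effects were compared across classes with at least 100 cells per label for the fixed lists and for genes picked after their values were seen, and every test of an explanation in this part was chosen only after the result it bears on had been seen.

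Hashtags that the labels do not name carried signal: 5325 barcodes had the Gt hashtag and 6752 the EH2 hashtag, more than the 4807 with WT. Their cells entered no comparison. MHC class II genes went opposite ways in classical monocytes and endothelial cells, by intervals that lie on opposite sides of 1, and the difference itself was not tested. In classical monocytes H2-Aa had a ratio of 0.404 against 2.05 in endothelial cells, H2-Ab1 0.417 against 2.15, H2-Eb1 0.228 against 2.28, and the summed list 0.555 against 2.65. The list of cell types other than endothelial had a ratio of 0.466 in fibroblasts and 2.70 in endothelial cells, a difference that was not tested and in which 1 cKO-labelled cell held most of the endothelial Scgb1a1 count and 1 WT-labelled fibroblast held 320 haemoglobin UMIs. The list was fixed for endothelial cells and holds the fibroblast markers Col1a1 and Dcn. Its ratio in fibroblasts therefore includes genes of the class itself, and the weight of the haemoglobin UMIs in it was not computed.

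Neutrophils were scarcer among cKO-labelled cells. With hashtag counts scaled to their medians and the rule of 3 times, the neutrophil ratio was 0.359 (0.311 to 0.413), which argues against hashtag assignment as the whole cause, although the unscaled rule of 3 times moved it to 0.649. Without the limits on UMIs and mitochondrial share, and with a lower limit on genes, the neutrophil ratio was 0.377 (0.333 to 0.425). This argues against a loss of shallow neutrophils to the cell filter used here. A loss at the earlier cell calling or at the hashtag minimum could not be seen by this test. More blood left in the WT-labelled lung would lower other blood cells under the cKO label too and cannot be told apart from a difference between the mice. The interval of the T-cell ratio of 1.08 (0.949 to 1.24) includes 1, and this share over all cells rises as neutrophils fall. Among cells other than neutrophils the T-cell ratio was 0.891 (0.781 to 1.02), an interval that also includes 1. Classical monocytes (0.425) go with more blood, while B cells (2.77) and nonclassical monocytes (1.82) go the other way. Haemoglobin had 9925 and 228 UMIs but 146 and 228 without 6 WT-labelled cells, and blood and the genotype stay open.

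Rp1 was high in cKO-labelled endothelial cells. RNA of ciliated cells is argued against by 6 of their markers, whose median stood at 0.0648% of the ciliated level in these cells, with Tppp3 alone at 4.15%, against 50.6% for Rp1. An Rp1 allele raised by a like fold in every cell type is argued against by the ratio of 1.15 (0.820 to 1.63) in ciliated cells, and one raised by a like level by T, B and NK cells, with an upper bound of at most 9.64 CPM, although fibroblasts (0 and 25 UMIs), pericytes (0 and 24) and neutrophils (5 and 6) also had more Rp1 under the cKO label. The endothelial factor Sox7 was counted there too, with 25 and 21, 12 and 19, and 4 and 5 UMIs. Endothelial RNA in those classes and Rp1 of their own were therefore not told apart. Transcription that starts at a recombined Sox17 locus and runs on downstream cannot be told apart from activation of Rp1 itself: Gm37381, the next gene downstream, had 1 and 32 UMIs in endothelial cells, but it took 2.25% (1.54 to 3.16) of the UMIs of both genes there and 5.30% (2.31 to 10.2) in ciliated cells. Both stay open, and nothing here shows the structure of the allele.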

How the results depend on the processing

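The alternatives by denominator, scaled hashtags, general capillary cells alone, cluster 14 as endothelial, the arterial cluster of all cells at resolution 2 and single cells, and all alternatives for single genes, were chosen after seeing the data, and the others were planned. For the main results, 94 alternative values stayed within the counting interval of the reported value (or, for lists, within a distance of the width of the random range divided by 2), 8 moved beyond it and 1 changed direction (counted only where the reported interval excludes 1, or a list lies outside its random range). Of those 94, 12 for E2f1, 10 for cycling and 8 for the arterial share stayed within wide intervals that few values could leave. The intervals of E2f1 (0.695 to 7.96) and cycling (0.291 to 6.82) include 1, so neither could count as changed in direction. The endothelial ratio was 1.06 with at least 1000 genes, 1.29 with scaled hashtag counts and 0.963, on the other side of 1, among cells other than neutrophils, which follows from the smaller denominator. The neutrophil ratio was 0.426 with at least 1000 genes and 0.649 with the rule of 3 times, and the B-cell ratio 4.09 with that rule and 2.28 among cells other than neutrophils. In general capillary cells alone, the Sox17 ratio was 1.05 and the MHC class II median 1.41. For the remaining results, 299 values stayed, 26 moved and 2 changed direction: Scgb1a1 had a ratio of 0.943 with scaled hashtags and 0.732 without the cell that held most of its UMIs, and that cell sets its direction. Except for the 2 ratios that rest on the denominator, the cause of these shifts was not tested. The Sox17 ratio ranged from 0.865 to 1.05, the E2f1 ratio from 1.59 to 4.13, the arterial ratio from 1.90 to 5.80 and the cycling ratio from 0.527 to 2.34. Rp1 ranged from 27.1 to 59.2 and Cd74 from 3.23 to 3.58. General capillary cells alone, with 61.0 and 4.02, were not among the settings for these genes. No arterial cluster formed at Leiden resolution 0.5, and E2f1 and cycling gave no value with the rule of 3 times. Subtracting the lowest level over classes moved nothing, since that level was 0 and the setting tests nothing. Depth limits E2f1 (5 and 11 UMIs) and cycling (4 and 5 cells). No paired analysis was possible because each label stands for 1 sample and no test was made.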

Other observations

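The observations in this part were chosen after seeing the data. Some further values in myeloid cells stood apart from 1. In alveolar macrophages the G1/S and E2F target list had a summed ratio of 0.624, and Cd74 a ratio of 2.22 (1.83 to 2.68). In classical monocytes Cd74 had a ratio of 0.678 (0.609 to 0.755). The pro-apoptotic and anti-apoptotic lists had ratios of 0.742 and 0.780 in classical monocytes and 0.918 and 0.899 in endothelial cells.

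Gdpd3 was lower in cKO-labelled cells of every class with at least 200 cells per label, with ratios of 0.114 in endothelial cells, 0.134 in general capillary cells, 0.182 in neutrophils, 0.0316 in B cells, 0.0561 in NK cells and 0.00645 in T cells. Sult1a1, also among the lowest endothelial genes, lies near it on chromosome 7. Glp1r, another of the lowest, lies at 30901817 to 30940791 on chromosome 17, next to Dnah8. No explanation was tested for these positions.

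Glo1 and Btbd9, neighbours on chromosome 17, were higher in cKO-labelled cells of many classes. Both had intervals above 1 in T, B and NK cells, both monocyte classes, alveolar macrophages, pericytes and general capillary, aerocyte and venous cells. Fibroblasts had 2.00 (1.36 to 2.98) for Glo1 and 1.07 (0.888 to 1.28) for Btbd9, and neutrophils 2.45 (2.27 to 2.63) for Btbd9 and 10 and 4 UMIs of Glo1. Dnah8 beside them was higher in T cells (4.59) and lower in endothelial cells (0.532, 0.390 to 0.720). In T cells, 17 flanking genes had a median ratio of 1.04, with single genes from 0.759 to 1.56. No explanation is offered for this stretch.

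Haemoglobin UMIs were concentrated in few cells. Of 9925 haemoglobin UMIs in WT-labelled cells, 9779 lay in 6 cells with at least 100 each and 146 in the others, and the cKO-labelled cells had 228 in total and 0 such cells. Xist, expressed from the inactive X chromosome, stood at 41.5 and 53.9 CPM over all cells and the Y-linked Ddx3y at 149 and 131 CPM, so both labels held RNA of both kinds.

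Clustered alone, endothelial cells formed a cluster of 13 WT-labelled and 171 cKO-labelled cells, led by Adam23, Ntrk2, Rp1, Slc6a6 and Edn1 among others, and another of 159 and 25, with Sult1a1 among its leading genes. Each holds mostly cells of 1 label, and its leading genes include endothelial differences given above, so it gives no separate check of them. Neither reached the 3 markers that the name of an endothelial class needs. Nor did the clusters of 261 and 129, 184 and 195, 190 and 101, 136 and 93, and 4 and 3 cells.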
